A study of Homo sapiens with 4 samples.

How the data were processed

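Total RNA of HCT116 cells was extracted with TRIzol, converted to labelled cDNA with the WT PLUS reagent kit, tagged with biotin and hybridised to Affymetrix whole-transcriptome arrays, per the labels' protocols. The 4 arrays comprised 2 of cells transfected with a control siRNA and 2 of cells transfected with an siRNA against CDK8, each for 48 h at 50 nM. Groups and replicate numbers were taken from the sample titles, which call the replicates biological. The control group was read as control siRNA from a treatment label of control and a protocol that transfects siRNA, and the labels do not say what its sequence is. No label says whether they came from separate cultures or days, so p-values measure the spread between these samples.

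The deposited values were log2 signals from RMA in Affymetrix Expression Console, per the submitters' processing notes, and their versions and settings are not given in the sources used here. RMA subtracts background, equalises arrays and summarises the probes of each probe set, which compresses fold changes at low signal and assumes that arrays share a similar overall distribution. The table held 70523 rows with 2 decimals, of which 67528 were transcript clusters. The other 2995 rows (spike-in and control features, and exon or junction regions) were left out of the tests. Signals lay between 1.95 and 19.93, and no detection calls were used. The number of arrays limits the precision.

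Gene symbols came from the annotation of the array platform, which listed 25324 of the transcript clusters, 23781 with 1 symbol and 1543 with several. The remaining 42204 were unnamed here. Symbols were updated through a RefSeq gene table of the assembly GRCh38.p14, in which 23777 of the 23781 matched and 306 changed. The build behind the array design is not given in the sources used here, so no coordinates are printed. For the 528 of 22411 genes with more than 1 probe set, the probe set with the highest mean signal was used, and 5 genes had probe sets called in opposite directions, 0 of them named in the text. Genes were tested where the mean over the 4 arrays reached 4.28, the median of all transcript clusters, which left 13956.

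Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The median standard error of a log2 difference was 0.0832, and the smallest called difference was 0.21. The median log2 difference over tested genes was 0.005. Of 40 gene lists 37 had at least 5 tested members and were compared with all other genes by limma's camera with a preset correlation of 0.01, again with Benjamini-Hochberg adjustment. The lists were Mediator kinase module and core, β-catenin/TCF, p53, immediate early, hypoxia, glycolysis, interferon-stimulated, NF-κB, E2F, G2/M, cholesterol, lipid synthesis, ATF4, endoplasmic reticulum chaperones, heat shock, NRF2, YAP/TAZ, TGF-β/BMP, Notch, epithelial, mesenchymal, intestinal, ERBB/MAPK, ribosome biogenesis, respiratory chain, lysosome, metallothionein, RNA interference, reference, fibroblast, blood cell and endothelial genes, and symbol patterns for ribosomal proteins, histones, snoRNAs, microRNA loci, ZNF genes, mitochondrial ribosomal proteins and the proteasome. Counts adjusted over the list alone used the members of a list as the family of tests.

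Named genes followed a rule: the kinase module, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, and up to 4 members of each list with the smallest p. Genes named outside that rule are given as such. The groups, tests, lists, naming rule and alternatives were set before the data were examined, except where stated. Figures were drawn with matplotlib 3.10.9.

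The fit was tested on simulated data for the 13956 genes, with 200 changed one by one and a list of 25 changed by a log2 of 0.5. Of the 200 it recovered 0% of 50 genes changed by a log2 of 0.25, 10% of 50 changed by 0.5, 86% of 50 changed by 1 and 100% of 50 changed by 2, and called 4 of 13731 unchanged genes. The simulation changed far fewer genes than the 6908 called in the data, and the adjusted threshold is stricter when fewer genes change. These rates therefore do not give the power or the false calls of the comparison itself. Alternatives were no filter, a filter at the 75th percentile (6.17), quantile normalization, centring of arrays, eBayes with a trend or with robust settings, other rules for probe sets, the replicate number as a block, leaving out each array, other thresholds, and camera with an estimated correlation or fry in place of camera with the preset one. Camera with an estimated correlation also uses the 2 residual degrees of freedom of the fit, so it can lose calls whatever the correlation. fry tests whether a list's genes, each scaled by its spread, move on balance 1 way and does not compare them with other genes.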

Results

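The series measured RNA in HCT116 cells, an established human colon cancer cell line, after RNA interference against CDK8. CDK8 is the cyclin-dependent kinase of the Mediator kinase module, a detachable part of the complex that links transcription factors to RNA polymerase II. Cells had been transfected for 48 h with 50 nM of an siRNA against CDK8 or of a control siRNA, and each group held 2 arrays that the labels describe as biological replicates. The design holds a single comparison, CDK8 siRNA against control siRNA, which asks which transcripts differ in level after transfection of the CDK8 siRNA. With 1 group with CDK8 siRNA it cannot separate loss of CDK8 from other effects of that siRNA. Median signals over all transcript clusters were 4.24 and 4.24 (log2) on the control arrays and 4.32 and 4.31 on the CDK8 siRNA arrays. The control arrays correlated with r = 0.998 and the CDK8 siRNA arrays with r = 0.997 across the 13956 tested genes, against 0.963 to 0.965 between arrays of different groups. Changes below are log2 differences of CDK8 siRNA minus control siRNA ± standard error from limma (n = 2 per group), and adjusted p-values are those of limma with Benjamini-Hochberg adjustment.

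CDK8 itself fell from 10.02 ± 0.04 to 7.35 ± 0.14 (mean log2 signal ± SD, n = 2 per group), a change of -2.67 ± 0.09 or 6.34-fold (adjusted p = 4.43e-05). Its paralog CDK19, which takes the place of CDK8 in the module, fell 2.14-fold (-1.10 ± 0.09, adjusted p = 3.29e-04). CCNC, the cyclin that activates both kinases, rose 1.83-fold (0.88 ± 0.07, adjusted p = 4.16e-04). The MED13 scaffold, which joins the module to Mediator, rose 3.89-fold (1.96 ± 0.09) while its paralog MED13L fell 2.35-fold (-1.24 ± 0.12). MED12, which activates the kinase, fell 1.94-fold (-0.96 ± 0.09), and MED12L at -0.26 ± 0.10 did not pass (adjusted p = 0.0700). Of the 7 module genes 2 rose, 4 fell and 1 did not pass, or 2 and 5 adjusted over the list alone. The module as a list, with CDK8 itself among its members, had no call (camera adjusted p = 0.240), but passed as lower under fry (adjusted p = 0.0335). Among 24 tested subunits of the Mediator core 10 rose, 4 fell and 10 did not pass, with the same counts adjusted over the list alone. MED10 (1.48 ± 0.07), MED8 (1.26 ± 0.10) and MED21 (0.93 ± 0.09) were among the risers. The core list as a whole lay higher (median 0.19, adjusted p = 0.0370; adjusted p = 0.626 with an estimated correlation). That call was lost without control siRNA replicate 2 (adjusted p = 0.0505) and without CDK8 siRNA replicate 1 (adjusted p = 0.0546), and with a filter at the 75th percentile of signal (adjusted p = 0.0524).

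**Figure D1:**
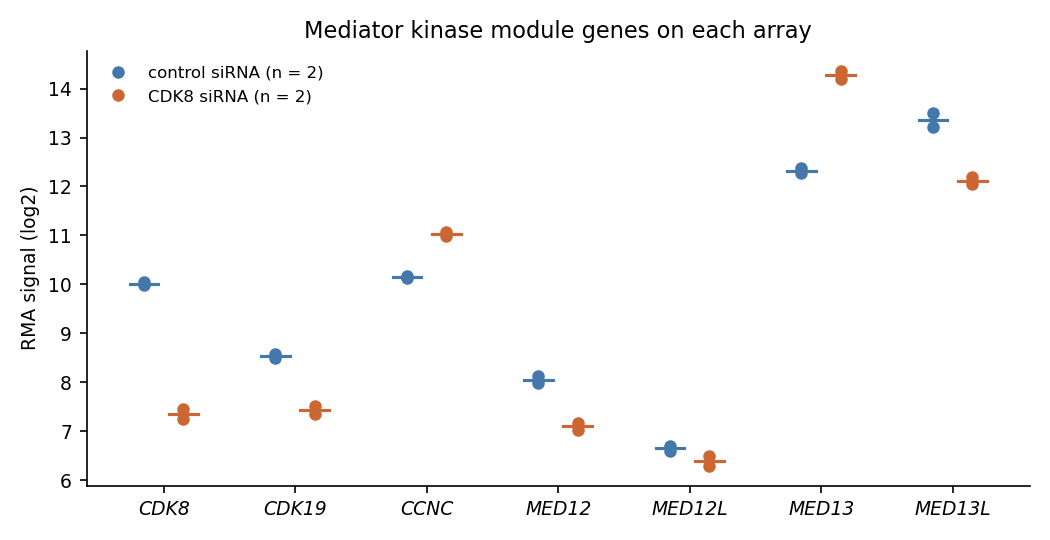
RMA signal (log2, vertical axis) of the 7 Mediator kinase module genes (horizontal axis) on each array, with a dot per array and a line at the mean of the 2 arrays of a group. CDK8 lay at 10.02 with control siRNA and 7.35 with CDK8 siRNA, and the MED12L groups (6.65 and 6.39) were the pair that did not pass the test.

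Among tested genes with a transcript cluster of their own, the largest rises were those of the chemokine genes CXCL8 and CCL20, which attract neutrophils and lymphocytes. CXCL8 went from 5.32 ± 0.11 to 13.69 ± 0.19 (mean log2 signal ± SD, n = 2 per group), a 330-fold rise (8.37 ± 0.12, adjusted p = 2.23e-05), and CCL20 rose 226-fold (7.82 ± 0.36, adjusted p = 7.89e-05). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose 55.9-fold (5.81 ± 0.14). The cell surface proteoglycan gene SDC4 rose 26.6-fold (4.74 ± 0.10), the carboxypeptidase gene CPA4 23.5-fold (4.56 ± 0.13) and GALNT5, whose product starts mucin-type O-glycosylation, 22.2-fold (4.48 ± 0.08). SLC2A3, a glucose transporter, rose 21.5-fold (4.43 ± 0.10). The next were TNFRSF9, a receptor of the tumour necrosis factor family (15.8-fold, 3.99 ± 0.11), and the matricellular gene CCN1 (14.5-fold, 3.86 ± 0.09). They were followed by the syntaxin gene STX11 (14.5-fold, 3.86 ± 0.10), NFKBIA, which encodes the inhibitor of NF-κB (14.0-fold, 3.81 ± 0.11), and the lipase gene LIPH (13.6-fold, 3.77 ± 0.08). The control mean of TNFRSF9 (3.83) lay under the filter level of 4.28, where RMA signals compress fold changes.

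Of the same genes SOX4, a transcription factor gene, fell the most, 15.2-fold from 11.81 ± 0.07 to 7.88 ± 0.21 (mean log2 signal ± SD, n = 2 per group; change -3.93 ± 0.12, adjusted p = 3.31e-05). MAPRE1, which encodes a protein of growing microtubule ends, fell 13.3-fold (-3.74 ± 0.09), the polarity scaffold gene MPP7 11.9-fold (-3.57 ± 0.08) and the cell cycle gene PRR11 11.7-fold (-3.55 ± 0.08). KITLG, the ligand of the receptor KIT, fell 10.9-fold from the high signal of 16.67 (-3.45 ± 0.10). PAK2, a kinase downstream of RAC and CDC42, fell 10.4-fold (-3.38 ± 0.07), and SKP2, the ubiquitin ligase subunit that marks the CDK inhibitor p27 for degradation, fell 9.61-fold (-3.27 ± 0.12). Falls of 7.86-fold to 9.51-fold were measured for 5 genes. These were GPD2 (-3.25 ± 0.08), a mitochondrial dehydrogenase, ETV1 (-3.25 ± 0.11), an ETS transcription factor, STN1 (-3.18 ± 0.10), a telomere maintenance factor, DUSP6 (-2.99 ± 0.17), a phosphatase of ERK, and TOMM34 (-2.98 ± 0.10), a cochaperone of mitochondrial import. Adjusted p-values of these 24 genes lay between 2.23e-05 and 1.36e-04, and 25 genes fell more than CDK8 did.

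In all, 3229 of 13956 tested genes were higher with CDK8 siRNA and 3679 were lower, while 7048 did not pass. The groups did not overlap in 10426 genes (74.7%, where chance gives 33.3% for 2 against 2). At least 2-fold changes were called for 713 genes upward and 787 downward, and at least 8-fold changes for 24 and 10. With 1 array left out the counts fell to 1553 higher and 1778 lower without control siRNA replicate 1, 1377 and 1745 without control siRNA replicate 2, 2041 and 2414 without CDK8 siRNA replicate 1, and 2097 and 2321 without CDK8 siRNA replicate 2.

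**Figure D2:**
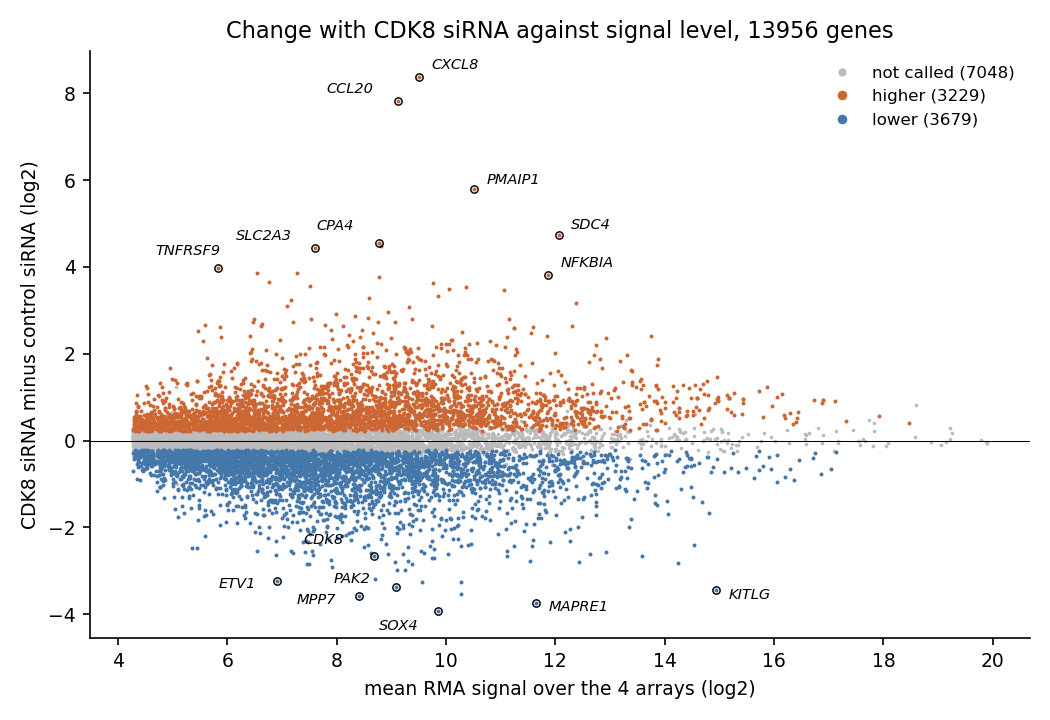
Log2 difference of CDK8 siRNA minus control siRNA (vertical axis) against the mean log2 RMA signal over the 4 arrays (horizontal axis), with a point per tested gene, coloured by limma's call at an adjusted p of 0.05. The 3229 higher and 3679 lower genes spread over most of the signal range, with CXCL8 at 8.37 and SOX4 at -3.93 as the extremes.

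Innate immune and inflammatory genes rose together. Of 41 interferon-stimulated genes on the array 26 were tested. The filter uses the mean of all 4 arrays, so a gene silent in control cells could pass it only through a rise. Of the 26 tested 22 rose, 0 fell and 4 did not pass (24 and 0 adjusted over the list alone), with a median of 1.08 and a camera adjusted p of 7.94e-10 (adjusted p = 0.259 with an estimated correlation). IFIH1 and RIGI, the cytoplasmic sensors of double-stranded RNA, rose 9.38-fold (3.23 ± 0.07) and 3.28-fold (1.72 ± 0.08), SAMD9, an antiviral factor, 7.52-fold (2.91 ± 0.13) and IFIT5 3.22-fold (1.69 ± 0.08). The interferon genes IFNB1 and IFNL1, members of that list named outside the rule, lay under the filter level with mean signals of 3.23 and 3.98. Tested without the filter, they differed by 0.005 (adjusted p = 0.982) and 0.205 (adjusted p = 0.280). Among 19 tested of 23 NF-κB and inflammatory genes on the array 18 rose, 0 fell and 1 did not pass, over all genes and adjusted over the list alone (median 1.05, adjusted p = 3.19e-09; adjusted p = 0.259 with an estimated correlation). Besides CXCL8, CCL20 and NFKBIA these included TNFAIP3, a feedback inhibitor of NF-κB (8.63-fold, 3.11 ± 0.09), and TNFAIP2 (6.32-fold, 2.66 ± 0.10). CXCL1, a further neutrophil chemokine named after its value was seen, rose 6.96-fold (2.80 ± 0.19). Of the blood cell markers 3 had enough signal to be tested. CD68, a lysosomal membrane protein of macrophages that other cells also make, rose 2.57-fold (1.36 ± 0.11, adjusted p = 3.39e-04), while 0 fell and 2 did not pass, with the same counts adjusted over the list alone. Under the filter level, PTPRC, the pan-leukocyte marker, differed by 0.08 and LYZ by -0.04, both named outside the rule. Fibroblast markers gave 1 higher of 3 tested, the collagen gene COL1A1 (0.26 ± 0.07, adjusted p = 0.0287), and endothelial markers 1 of 2, the adhesion gene ESAM (0.28 ± 0.07, adjusted p = 0.0194), with 0 lower in either list and the same counts adjusted over the list alone. The COL1A1 call was lost with quantile normalization (adjusted p = 0.0574) and with any array left out, with adjusted p = 0.0840 and 0.135 without control siRNA replicate 1 and 2 and 0.0979 and 0.0977 without CDK8 siRNA replicate 1 and 2. The ESAM call was lost with any array left out, with adjusted p = 0.0852 and 0.107 without control siRNA replicate 1 and 2 and 0.0710 and 0.0641 without CDK8 siRNA replicate 1 and 2.

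Cell cycle genes fell almost as a block. Of 39 tested G2/M and mitosis genes 38 fell, 0 rose and 1 did not pass, over all genes and adjusted over the list alone (median -0.91, adjusted p = 2.03e-13; adjusted p = 0.259 with an estimated correlation). HMMR, a spindle-associated protein gene, fell 6.89-fold (-2.79 ± 0.10), the mitotic cyclin genes CCNB2 5.21-fold (-2.38 ± 0.08) and CCNB1 3.04-fold (-1.61 ± 0.07), and the mitotic kinase gene AURKA 3.26-fold (-1.71 ± 0.08). Among 38 E2F and S phase genes 34 fell, 0 rose and 4 did not pass, with the same counts adjusted over the list alone (median -0.85, adjusted p = 3.71e-10; adjusted p = 0.524 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell 3.89-fold (-1.96 ± 0.10) on its brighter probe set. Its other probe set, near the filter level with a mean signal of 4.60, stood at -0.07 ± 0.09 (adjusted p = 0.583), and the mean of both gave -1.02 (adjusted p = 5.29e-04). The G1/S cyclin gene CCNE1 fell 2.93-fold (-1.55 ± 0.08) and the replication genes GINS2 and CHAF1A 2.89-fold each (-1.53 ± 0.07 and -1.53 ± 0.08). Of 3 genes named after their values were seen, the proliferation marker MKI67 fell 2.45-fold (-1.29 ± 0.10) and CDK4 fell 4.81-fold (-2.27 ± 0.13), whereas CDK6, the paralog of CDK4, rose 2.27-fold (1.19 ± 0.10). Of 33 histone genes 16 fell, 3 rose and 14 did not pass (16 and 4 adjusted over the list alone; median -0.35, adjusted p = 0.0254; adjusted p = 0.634 with an estimated correlation). The histone call was lost without CDK8 siRNA replicate 2 (adjusted p = 0.0835). H2AC21 fell 5.45-fold (-2.45 ± 0.10) and the linker histone H1-4 1.95-fold (-0.96 ± 0.07), while the testis type H1-6 rose 2.37-fold (1.25 ± 0.11).

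Targets of p53 rose in 17 of 25 tested genes, fell in 1 and did not pass in 7, or 17 and 2 adjusted over the list alone (median 0.61, adjusted p = 1.19e-04; adjusted p = 0.524 with an estimated correlation). GDF15, a stress-induced cytokine, rose 5.56-fold (2.48 ± 0.10), PLK2 4.99-fold (2.32 ± 0.10), MDM2, the ubiquitin ligase of p53, 3.03-fold (1.60 ± 0.08) and SESN2 2.45-fold (1.30 ± 0.08). CDKN1A, the CDK inhibitor p21, and BAX, a pro-apoptotic gene, were named after their values were seen. CDKN1A rose 1.55-fold (0.64 ± 0.13, adjusted p = 0.0106) and BAX stood at 0.02 ± 0.08 (adjusted p = 0.898). The CDKN1A call was lost with any array left out, with adjusted p = 0.0517 and 0.109 without control siRNA replicate 1 and 2 and 0.146 and 0.0887 without CDK8 siRNA replicate 1 and 2. YAP/TAZ targets rose in 13 of 20 tested genes, fell in 2 and did not pass in 5, with the same counts adjusted over the list alone (median 0.94, adjusted p = 2.62e-04; adjusted p = 0.439 with an estimated correlation). They were led by CCN1, the kinase gene NUAK2 (12.6-fold, 3.65 ± 0.15) and GADD45B (4.30-fold, 2.11 ± 0.07). Immediate early genes split into 19 that rose, 8 that fell and 2 that did not pass, also adjusted over the list alone (median 0.47, adjusted p = 0.00769; adjusted p = 0.519 with an estimated correlation). The zinc finger genes KLF6 (11.6-fold, 3.53 ± 0.07) and ZFP36 (11.2-fold, 3.48 ± 0.09) and the AP-1 gene JUN (3.42-fold, 1.78 ± 0.07) rose, and DUSP6 was among those that fell. Of the 29 tested members of that list 13 also stood in another list.

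Among β-catenin/TCF targets, which are constitutively active in HCT116, 10 of 15 tested genes fell, 4 rose and 1 did not pass, with the same counts adjusted over the list alone. The list had no call (median -0.37, camera adjusted p = 0.0685), but passed when arrays were centred on their medians (adjusted p = 0.0429). It also passed as lower under fry, which tests the list by itself (adjusted p = 0.00565). Besides SOX4, the feedback inhibitors RNF43 and AXIN2 fell 3.64-fold (-1.87 ± 0.08) and 2.01-fold (-1.01 ± 0.07), and the stem cell factor SOX9 fell 3.84-fold (-1.94 ± 0.18). The proliferation genes CCND1 and MYC rose 1.83-fold (0.87 ± 0.10) and 1.41-fold (0.50 ± 0.11, adjusted p = 0.0123), and TCF7L2, a TCF factor that binds β-catenin, fell 2.60-fold (-1.38 ± 0.09), all 3 named after their values were seen. The MYC call was lost with any array left out, with adjusted p = 0.0585 and 0.117 without control siRNA replicate 1 and 2 and 0.135 and 0.0837 without CDK8 siRNA replicate 1 and 2.

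Hypoxia targets rose in 14 of 26 tested genes, fell in 4 and did not pass in 8, or 15 and 4 adjusted over the list alone (median 0.37, adjusted p = 0.00769; adjusted p = 0.519 with an estimated correlation). Besides SLC2A3 these included INSIG2, a sterol sensor (4.48-fold, 2.17 ± 0.10), ERO1A, an oxidase of protein folding (3.36-fold, 1.75 ± 0.09), and NDRG1 (2.88-fold, 1.53 ± 0.08). Glycolysis genes fell in 12 of 18, rose in 2 and did not pass in 4, or 12 and 3 adjusted over the list alone. HK2, a hexokinase, was 2.34-fold lower (-1.23 ± 0.09). The glycolysis list had no call (adjusted p = 0.0627), but passed with centred arrays (adjusted p = 0.0395) and without the filter on signal (adjusted p = 0.00835). ATF4 targets of the integrated stress response rose in 13 of 27, fell in 5 and did not pass in 9, or 14 and 5 adjusted over the list alone (median 0.28, adjusted p = 0.0262; adjusted p = 0.634 with an estimated correlation). The cystine transporter gene SLC7A11 rose by 3.17 ± 0.09 (log2) and ASNS, asparagine synthetase, 2.13-fold (1.09 ± 0.07), while AARS1, alanyl-tRNA synthetase, fell 3.80-fold (-1.93 ± 0.12). The ATF4 call was lost without control siRNA replicate 2 (adjusted p = 0.0505), without CDK8 siRNA replicate 1 (adjusted p = 0.0543) and without the filter (adjusted p = 0.0528). Metallothioneins, which bind zinc and copper, fell in 8 of 10 with 0 higher and 2 not passing, also adjusted over the list alone (median -0.74, adjusted p = 9.10e-04; adjusted p = 0.613 with an estimated correlation). MT1F fell 3.93-fold (-1.98 ± 0.07) and MT1H 2.09-fold (-1.07 ± 0.09). Cytosolic heat shock genes fell in 8 of 13, rose in 2 and did not pass in 3, also adjusted over the list alone (median -0.55, adjusted p = 0.0159; adjusted p = 0.519 with an estimated correlation). Among them were the chaperone gene HSPA4 (3.31-fold, -1.73 ± 0.07) and HSF1, the heat shock transcription factor (2.06-fold, -1.05 ± 0.07).

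Proteasome subunits rose in 17 of 33 tested genes, fell in 3 and did not pass in 13, or 21 and 5 adjusted over the list alone (median 0.39, adjusted p = 0.00153; adjusted p = 0.634 with an estimated correlation). PSMC4, an ATPase of the regulatory particle, rose 3.04-fold (1.61 ± 0.14) and PSMB2, a core subunit, 2.32-fold (1.22 ± 0.09). Lysosome and autophagy genes rose in 11 of 26, fell in 4 and did not pass in 11, also adjusted over the list alone (median 0.16, adjusted p = 0.0283; adjusted p = 0.634 with an estimated correlation). The autophagosome gene GABARAPL1 rose 4.89-fold (2.29 ± 0.07), the lysosomal membrane gene LAMP2 4.68-fold (2.23 ± 0.08) and the protease gene CTSL 3.41-fold (1.77 ± 0.07). The lysosome call was lost without control siRNA replicate 2 (adjusted p = 0.0550) and without CDK8 siRNA replicate 1 (adjusted p = 0.0546).

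By camera with its preset correlation, lists of noncoding RNAs and of ribosomal proteins lay higher than the other tested genes. Small nucleolar and Cajal body RNAs, which guide the modification of ribosomal and spliceosomal RNA, rose in 103 of 168 tested genes, fell in 2 and did not pass in 63, or 109 and 2 adjusted over the list alone (median 0.63, adjusted p = 7.06e-13; adjusted p = 0.613 with an estimated correlation). SNORA72 rose 2.60-fold (1.38 ± 0.08) on its brightest probe set and by 0.78 (adjusted p = 0.00636) as the mean of its probe sets. SNORD72 rose 2.53-fold (1.34 ± 0.09) and SCARNA3 2.20-fold (1.14 ± 0.07). Near copies with the same values, such as SNORD3B-1 and SNORD3B-2 (0.925 each), were counted separately. MicroRNA precursor loci, which the array reads as long transcripts and not as mature microRNAs, rose in 82 of 440, fell in 23 and did not pass in 335, or 56 and 15 adjusted over the list alone (median 0.11, adjusted p = 0.0173; adjusted p = 0.524 with an estimated correlation). Without the filter their call was lost (adjusted p = 0.0807). By gene type, 18.8% of 431 microRNA genes were higher and 4.87% lower, against 23.0% and 29.8% of protein-coding genes. MicroRNA loci thus differed by fewer falls and not by a larger share of rises. Their median was near those of genes under the filter (0.06) and of unnamed transcript clusters (0.075). Whether a small upward shift of low signals adds to it was not tested for this list, though its call held under quantile normalization. MIR4521 fell 5.33-fold (-2.42 ± 0.08) and MIR553 rose 2.54-fold (1.35 ± 0.08). Cytosolic ribosomal protein genes rose in 15 of 53, fell in 3 and did not pass in 35, or 14 and 2 adjusted over the list alone (median 0.13, adjusted p = 0.0277; adjusted p = 0.634 with an estimated correlation). RPL9 was 1.56-fold higher (0.65 ± 0.07) and RPS25 1.79-fold lower (-0.84 ± 0.08). The ribosomal protein call was lost with quantile normalization (adjusted p = 0.0718), with a filter at the 75th percentile of signal (adjusted p = 0.0524) and without CDK8 siRNA replicate 1 (adjusted p = 0.0546). With fry in place of camera the calls of the small nucleolar RNAs (adjusted p = 0.0502), microRNA loci (adjusted p = 0.0551) and ribosomal proteins (adjusted p = 0.0622) were lost.

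**Figure D3:**
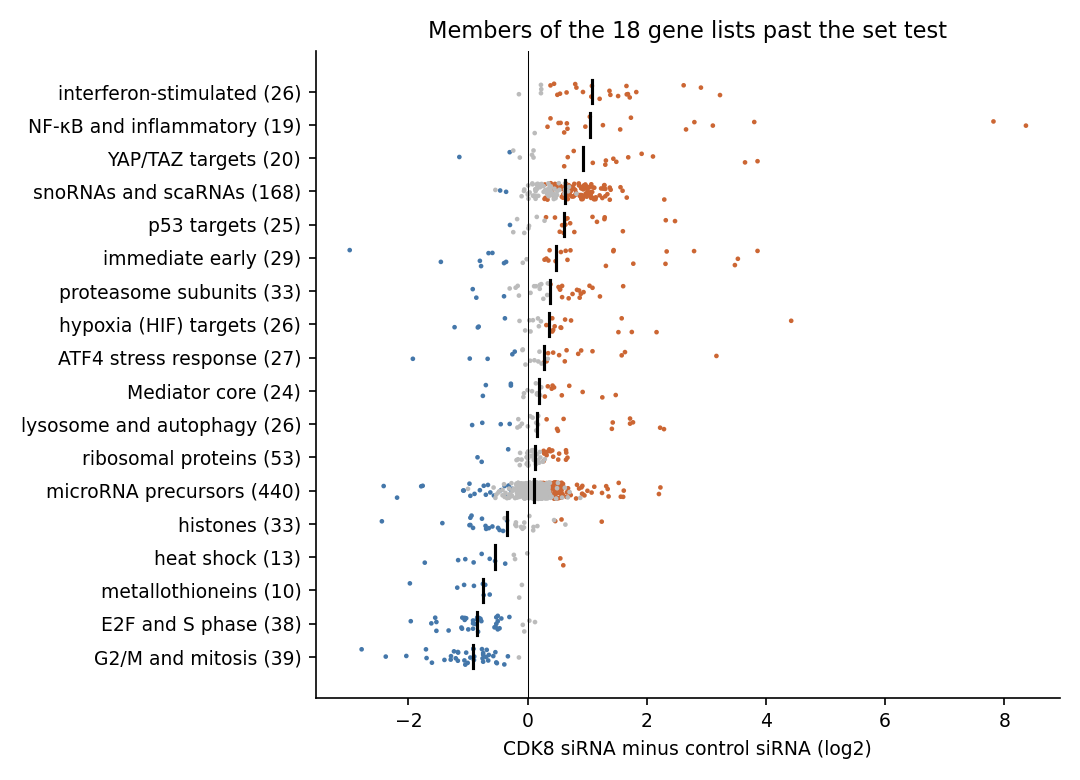
Log2 difference of CDK8 siRNA minus control siRNA (horizontal axis) of every tested member of the 18 gene lists past camera's test with its preset correlation, with the number of members beside each name (vertical axis). Dots are genes (orange higher, blue lower, grey not passed) and black bars are list medians, which run from 1.08 for interferon-stimulated genes to -0.91 for G2/M and mitosis genes.

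The other 16 tested lists had no call, with members that went both ways. Some passed under fry, which tests each list by itself (fry adjusted p in brackets). Epithelial (0.0355), mesenchymal (0.0206), NRF2 (0.0205), cholesterol (0.0414) and intestinal (0.0302) lists passed as higher. The TGF-β/BMP list also passed as higher (0.0104), although its median (-0.06) and mean (-0.07) log2 differences were negative, so its genes did not rise as a whole. ERBB/MAPK (0.0152), lipid synthesis (0.00565), Notch (0.0109) and RNA interference (0.0155) lists passed as lower. Epithelial adhesion genes (10 higher, 5 lower, 9 not passing of 24; 12 and 5 adjusted over the list alone; adjusted p = 0.137) held CDH1, E-cadherin, 7.11-fold higher (2.83 ± 0.11), the tight junction gene TJP1 5.17-fold higher (2.37 ± 0.09) and the desmosomal gene DSC2 5.41-fold lower (-2.44 ± 0.08). Mesenchymal genes (7 higher, 1 lower, 5 not passing of 13; 7 and 2 adjusted over the list alone; adjusted p = 0.107) included LGALS1, 2.23-fold higher (1.16 ± 0.09). ERBB ligand and MAPK feedback genes (6 higher, 10 lower, 4 not passing of 20, also adjusted over the list alone; adjusted p = 0.361) held the ligand HBEGF 2.94-fold higher (1.56 ± 0.07) beside DUSP6 and ETV1, which fell. NRF2 targets (9 higher, 5 lower, 1 not passing of 15; 9 and 6 adjusted over the list alone; adjusted p = 0.145) included TXNRD1, thioredoxin reductase, 4.14-fold higher (2.05 ± 0.08) and GCLM, of glutathione synthesis, 4.18-fold higher (2.07 ± 0.10). Cholesterol synthesis genes (7 higher, 4 lower, 9 not passing of 20, also adjusted over the list alone; adjusted p = 0.272) were led by SQLE, squalene epoxidase, 4.29-fold higher (2.10 ± 0.09). Lipid synthesis genes (3 higher, 6 lower, 4 not passing of 13; 3 and 7 adjusted over the list alone; adjusted p = 0.255) included FASN, fatty acid synthase, 3.15-fold lower (-1.66 ± 0.12). Chaperones of the endoplasmic reticulum (5 higher, 5 lower, 9 not passing of 19, also adjusted over the list alone; adjusted p = 0.676) included PDIA4, 5.35-fold lower (-2.42 ± 0.12). TGF-β and BMP targets (3 higher, 4 lower, 8 not passing of 15; 3 and 5 adjusted over the list alone; adjusted p = 0.676) held THBS1 6.28-fold higher (2.65 ± 0.07) and BMP4 3.01-fold lower (-1.59 ± 0.16). Notch genes (4 higher, 5 lower, 5 not passing of 14; 5 and 5 adjusted over the list alone; adjusted p = 0.877) held the ligand JAG1 4.79-fold lower (-2.26 ± 0.09).

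Intestinal differentiation genes had 4 higher, 1 lower and 4 not passing of 9 tested, also adjusted over the list alone (adjusted p = 0.170). The enterocyte peptidase gene DPP4 was 1.69-fold higher (0.76 ± 0.07). Ribosome biogenesis genes had 4 higher, 8 lower and 14 not passing of 26, also adjusted over the list alone (adjusted p = 0.906). CAD, of pyrimidine synthesis, was 2.15-fold lower (-1.11 ± 0.11). Respiratory chain genes had 6 higher, 12 lower and 17 not passing of 35, also adjusted over the list alone (adjusted p = 0.479). NDUFB5 was 2.06-fold lower (-1.04 ± 0.09). Mitochondrial ribosomal proteins had 16 higher, 17 lower and 40 not passing of 73, or 15 and 17 adjusted over the list alone (adjusted p = 0.802). MRPS27 was 3.05-fold lower (-1.61 ± 0.09). Zinc finger genes named ZNF had 73 higher, 90 lower and 183 not passing of 346, or 73 and 89 adjusted over the list alone (adjusted p = 0.906). ZNF704 was 5.88-fold lower (-2.56 ± 0.08) and ZNF699 3.57-fold higher (1.84 ± 0.07). RNA interference factors had 2 higher, 3 lower and 3 not passing of 8, also adjusted over the list alone (adjusted p = 0.440). TNRC6B, a partner of Argonaute, was 4.14-fold lower (-2.05 ± 0.07). Common reference genes had 5 higher, 2 lower and 5 not passing of 12, also adjusted over the list alone (adjusted p = 0.256). B2M was 2.11-fold higher (1.08 ± 0.08) and POLR2A 1.83-fold lower (-0.87 ± 0.09). With only 2 arrays per group, camera with a correlation estimated from the data kept 0 of the 18 list calls. That setting also judges each list on 2 residual degrees of freedom, so calls can be lost whatever the correlation. For G2/M (-0.0134), interferon-stimulated (-0.0274), NF-κB (-0.0537) and YAP/TAZ (-0.0279) genes the estimate lay under the preset 0.01. Their lost calls therefore do not show correlation among members. Other estimates lay above it, such as 0.283 for E2F genes and 0.349 for small nucleolar RNAs.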

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

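These results came from probe sets outside the comparison of named genes, with each kind fitted by itself in limma. Among 18009 unnamed transcript clusters over the filter level 1912 were higher with CDK8 siRNA and 1566 lower, with log2 differences from -5.18 to 8.79. Of 1020 transcript clusters that name several genes 203 were higher and 236 lower, with log2 differences from -2.05 to 8.11. Of 1450 exon and junction regions 225 were higher and 324 lower. Limma called 0 of 979 numbered control features (225 at an unadjusted p under 0.05), 0 of 63 ERCC spike-in features (5 at that level, median 0.10) and 0 of 8 bacterial and phage spike controls (4 at that level, median 0.19). For the numbered features and the bacterial and phage controls, that unadjusted share lies above the 0.05 that chance gives. Each kind also had its own spread estimate, so 0 calls does not show that the controls were equal between groups.

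The tests of other cell types, of low signals and of other splits of the arrays were chosen after the results were seen. Across the 45 tested interferon-stimulated and NF-κB genes the median difference was 1.07 and 40 genes were called higher. Scaling of the arrays is argued against because the highest of 10000 random lists matched on signal had a median of 0.25. Under quantile normalization 39 of the 40 calls held. That adds little, because RMA had already equalised the arrays and 6667 of 6906 calls held over all genes. Cells of another type stay open: the upper quartile of 15 blood cell markers was 0.10 against a lower quartile of 0.545 for the 45 genes, but only 3 of the 15 lay over the filter, and of 12 fibroblast markers (median 0.07) 3 were called higher without the filter. A response to the transfected RNA itself, which may raise interferon-stimulated genes (median 1.08) whatever the target, also stays open beside a response to loss of CDK8, since the design has 1 group with CDK8 siRNA and no further siRNA group, and the labels do not give the sequence of the control.

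Of 192 tested snoRNAs, scaRNAs and snRNAs 119 were higher and 2 lower (median 0.63), with near copies such as SNORD3B-1 and SNORD3B-2 counted separately. An upward shift of low signals is argued against by the 109 with a mean signal of 8 or more, whose median was 0.82 (quartiles 0.555 and 1.07), while genes under the filter had a median of 0.06. The host was taken as the smallest tested protein-coding or long noncoding gene that contains the short RNA, without regard to strand. It need not be the gene that makes the short RNA. The 22 short RNAs whose host so assigned fell (19 distinct hosts) had a median of 0.40 (quartiles 0.165 and 0.54), and 9 were called higher. Medians were 0.725 for 33 whose host rose and 0.695 for 43 whose host was not called. These values argue against host output as the whole cause only where the assigned host is the true one. Across 98 short RNAs with a tested host the differences correlated with those of the host, so a part in the pattern stays open (Spearman's rho 0.296, permutation p = 0.00281, 0.00562 after Benjamini-Hochberg adjustment over 2 correlations, across genes, which are not independent replicates). Recovery of short RNA that depends on length could still contribute and stays open, as does an effect of CDK8 loss: rho with length was 0.0446 across the 192 (permutation p = 0.536 raw and adjusted), which decides neither way.

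The falls of 25 genes exceeded that of CDK8. Unintended targets of the siRNA may be among them, along with genes downstream of CDK8. These cannot be told apart because the siRNA sequence and 3' UTR sequences were not used here. The same limit holds for all 3679 lower genes, CDK19 (-1.10) included, and for any genes that changed in turn. Other splits of the 4 arrays are too few for a share under 0.05: of 3 splits 1, the real one, called 6908 genes, and the highest other called 0 (27 and 28 genes at an unadjusted p under 0.05 by limma). Each other split also puts 1 control and 1 CDK8 siRNA array in both of its groups. A difference between control and CDK8 siRNA arrays then widens the spread within groups, so the 0 calls decide nothing.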

How the results depend on the processing

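All alternatives given here were planned. CDK8 kept its call in every setting, between -2.77 and -2.57 with 1 array left out (adjusted p 0.0221 to 0.0271). The counts of 3229 higher and 3679 lower genes became 713 and 787 when a 2-fold change was also required. With each array left out they ranged from 1377 to 2097 higher and from 1745 to 2414 lower, as the construction leaves 1 residual degree of freedom and assumes that the lone array varies like the other group. Centring the arrays turned the balance of calls, to 3736 higher and 3247 lower (53.5% higher, against 46.7%). Counts stayed within 1.5 times under the other filters, scalings, spread models, probe set rules and the threshold of 0.10, and every gene called both there and in the original fit kept its direction. Of list calls, camera with an estimated correlation kept 0 higher and 0 lower. It was estimated and tested on 2 residual degrees of freedom, which can lose calls whatever the correlation. In its place fry gave 16 higher against 13 in the main setting and 11 lower against 5, since it tests each list by itself. Under fry the TGF-β and BMP targets turned upward (adjusted p = 0.0104), although their median log2 difference was -0.06. The replicate numbers were shared by number alone (2 pairs, correlation of deviations 0.121). With the replicate block 2838 genes were higher and 3300 lower, CDK8 stayed at -2.67 (adjusted p = 0.00845), 12 lists were higher and 5 lower, and calls were lost for COL1A1 (adjusted p = 0.0505), MUC1 (adjusted p = 0.0544), CA2 (adjusted p = 0.0564) and the lysosome list (adjusted p = 0.0501). Signs reversed for genes near 0 that were called in no setting: under quantile normalization ACTA2 (-0.025) and NKG7 (-0.03), with centred arrays CD8A (0.005), and with 1 array left out ACTA2 (-0.01 to 0.04, reversed without CDK8 siRNA replicate 2), NKG7 (-0.04 to 0.10, without CDK8 siRNA replicate 1), BAX (-0.055 to 0.085, without control or CDK8 siRNA replicate 2) and RN7SK (-0.04 to 0.05, without control or CDK8 siRNA replicate 1). The cause was not tested. Of 2440 values of 189 other genes, taken by the naming rule or named in the text, under 13 alternatives 2370 kept direction and side of the threshold, and of 517 values of 37 lists 467 did. Signal near the RMA floor limits folds of genes with a low group mean.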

Other observations

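The set tests and genes given here were chosen after seeing the data: each of 204 symbol stems shared by 8 or more tested genes was compared with all other genes by camera, with Benjamini-Hochberg adjustment over the stems. Intraflagellar transport genes, which build cilia, fell in 15 of 17 with 0 higher and 2 not passing (median -0.72, adjusted p = 4.62e-05; adjusted p = 0.950 with an estimated correlation). IFT88 fell 3.14-fold (-1.65 ± 0.11, limma log2 difference ± SE, n = 2 per group), IFT74 2.82-fold (-1.50 ± 0.09) and IFT81 2.58-fold (-1.37 ± 0.08). DHX helicase genes fell in 10 of 15 with 0 higher and 5 not passing (median -0.51, adjusted p = 0.0307; adjusted p = 0.950 with an estimated correlation), among them the RNA helicase DHX9, 1.93-fold lower (-0.95 ± 0.09). HNRNPA genes, mostly pseudogene copies that can share probes with their parents, fell in 8 of 8 (median -0.54, adjusted p = 0.0417; adjusted p = 0.950 with an estimated correlation). DNAJB cochaperone genes rose in 8 of 9 with 0 lower and 1 not passing (median 0.40, adjusted p = 0.0417; adjusted p = 0.950 with an estimated correlation), such as DNAJB4, 1.94-fold higher (0.96 ± 0.08), opposite to the heat shock list, with which it shares DNAJB1.

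In the same set tests, chosen after seeing the data, small nuclear RNA genes and their copies (symbols starting with RNU) rose in 100 of 164, fell in 3 and did not pass in 61 (median 0.56, adjusted p = 1.24e-10; adjusted p = 0.950 with an estimated correlation). Copies of small nuclear and Y RNA genes can share probes, so these counts may hold repeated readings of the same RNA. The genes RNU4-2, RNU4-1, RNU5D-1, RNY1 and RN7SK were named after their values were seen. The spliceosomal RNU4-2 rose 2.27-fold from a signal of 14.06 (1.18 ± 0.08). Its brighter copy RNU4-1, with a mean signal of 17.32, rose by only 0.44 ± 0.11 (adjusted p = 0.0214). Of 22 tested genes typed as snRNA 15 were higher and 0 lower, and others such as RNU5D-1 (0.02 ± 0.09, adjusted p = 0.881) did not pass. Y RNA genes and their copies rose in 23 of 48, fell in 0 and did not pass in 25 (median 0.41, adjusted p = 8.50e-04; adjusted p = 0.950 with an estimated correlation), with RNY1 2.21-fold higher (1.15 ± 0.10). RN7SK, the RNA that holds the elongation kinase P-TEFb inactive, stood at 0.005 ± 0.07 (adjusted p = 0.964), with signals of 19.79 and 19.80 close to the highest on the arrays, where a change can be hidden. By gene type, 92 of 149 snoRNAs were higher and 2 lower, and 175 of 652 pseudogenes were higher and 56 lower, against 2647 higher and 3434 lower of 11510 protein-coding genes.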
